A study of Mus musculus with 18 samples.

How the data were processed

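Enterocyte RNA of 18 mice, 3 in each of 6 groups, was measured on 1-colour Agilent arrays. Per the submitters' processing notes the arrays were read with Agilent Feature Extraction; its version, the signal column, the background step and the choice of rows are not given in the sources used here. The deposited intensity values are whole numbers on a linear scale, reach 65501 and are at or below 0 in 432 cells, with no scaling between arrays that the values show. The authors' deposited table holds log2 fold changes per mouse for 51 genes against the mean of 3 controls, filtered and grouped by function per the file headers. The values depart from this in 3 cells, which are linear ratios (Uhrf1bp1 in POS mice), and 14 further cells, all in POS mice, could not be resolved. Gene names come from that table, and all 51 match a symbol in the GRCm38.p6 gene table; no coordinates are given because the files name no build. The other features have a number and no name here. Groups and replicate numbers come from the labels.

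Values were set to at least 1, since some are at or below 0, and log2 transformed. Group means over all 18 arrays were fitted in limma 3.58.1 (R 4.3.3) with eBayes without trend, and 9 comparisons were tested with Benjamini-Hochberg adjustment at 0.05. The tests, their alternatives and 41 gene lists were fixed before the data were examined. Values as deposited, with no scaling, were the fixed choice, and centred values stand beside them in the report. The rule for named genes takes up to 12 higher and 12 lower genes past the threshold or, where none passes, the 4 higher and 4 lower named genes with the smallest p, given as not past the threshold. Fewer are given where fewer named genes lie on that side. Apoa1, Csf2, Cd2, Nat2 and further genes quoted from the authors' deposited table were chosen after their values were seen.

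The choice of rows was made after seeing the data. In 1893 of 6914 rows at least 1 PCS cell is blank, and several columns from PC on do not appear to hold the mice they name. Those rows, with 8 named genes, were left out. By then 10 exploratory fits had been run, over both sets of rows and several settings. Limma called 0 features in each comparison with all rows and with the 5021 rows kept, and of the exploratory fits only the fit with array weights called any. All exploratory settings are among those in the closing section, which covers 10 planned and 8 added settings and 66 fits without a single array. The fold rule was also applied after seeing the data.

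Camera on gene lists needed 5 named members per list. Of the 41 lists, 4 hold 1 named gene each (Nat2, Apoa1, Csf2 and Cd2) and the rest hold none, so 0 lists were tested, and markers of other cell types could not be followed. Averaging features of the same gene had nothing to average.

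The fit was tested on simulated data for 5021 features with the real array brightness and normal noise equal in all groups. That noise was taken from the centred fit, so it spreads the extra noise of PO array 2 over every array. As deposited, simulated 8-fold changes were called in 0% of changed features for ADI against Ctr, 2% for PC, 10% for PO, and at most 46%, for the storage comparison. With centred arrays they were called in 76% for ADI, PC and PO against Ctr, 86% for PCS and 82% for POS, and 42% for the interaction. A count of 0 as deposited therefore says little about changes of that size. With centred arrays, simulated 2-fold changes were called in 2% to 24%.

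Whole numbers behind the deposited log2 folds were recovered as fractions with denominators up to 200000, using the smallest control sum that made all numbers of a gene whole. This rule can miss equal cells where all numbers share a factor, as it did for Thap1 and Chd3 in PC mice. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.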

Results

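The series measured messenger RNA in enterocytes scraped from the jejunum, the middle part of the small intestine, of male BALB/cOlaHsd mice that were 8 weeks old at the start. Each of 6 groups is represented by 3 mice, taken from 12 per group after 20 days of daily gavage, and each mouse has its own Cy3-labelled Agilent array. Control mice (Ctr) received water, and ADI mice received a mixture of 9 pesticides at the acceptable daily intake. PC and PO mice received 30 mg per day of flour from conventionally or organically grown potatoes, and PCS and POS mice received flour of the same kinds of potato under storage conditions. The label of POS mouse 3 alone gives day 27, with 7 days of what it calls resilience after the gavage, where the other labels give day 20. POS values therefore include a mouse that, by its label, was sampled 7 days after the gavage ended.

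The deposited intensity table has 6914 array features, of which 51 carry a gene name through the authors' deposited table of fold changes. The authors chose those 51 genes on these samples, so they are not independent evidence of any direction. Their intensities also differ between the 2 deposited tables, as described at the end. Tests used the 5021 features with a value on every array, 43 of them named. Array brightness differed widely: the median intensity over these features was 168, 184 and 256 in the control mice, 250, 147 and 37 in the ADI mice, and 90, 5 and 370 in the PO mice. PO array 2 had 84.2% of its values under 16, and its median Spearman correlation with the other arrays, across features, was 0.36. The median feature therefore differed from the controls by -0.90 (log2) in ADI, -1.55 in PC, -1.98 in PO, -0.16 in PCS and -0.53 in POS, and gene differences are given as deposited, with values relative to that shift named as such. The shift itself rests on few arrays: it was -0.13 in PO without PO array 2 and -3.46 without PO array 3, -0.097 in ADI without ADI array 3, 0.41 in PCS without PCS array 1 and -0.92 without PCS array 3, and 0.088 in POS without POS array 3 and -1.11 without POS array 2. The number of arrays limits the precision of every value.

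**Figure D1:**
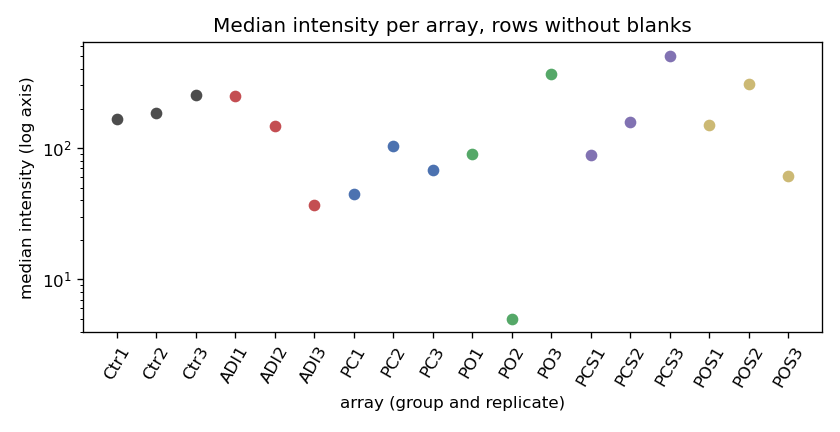
Median intensity of each of the 18 arrays over the 5021 features with a value on every array (vertical log axis, intensity units; horizontal axis, group and replicate). Points are single mice; PO array 2 lies lowest at 5 and PCS array 3 highest at 507.

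The pesticide mixture was compared with water. Plcb4 (feature 7153), a phospholipase C that cleaves membrane phosphoinositides, had a log2 intensity of 13.13 ± 1.77 (SD, n = 3) in ADI mice and 9.22 ± 3.86 (SD, n = 3) in controls. Its log2 difference was 3.91, with 1.95 when control array 2 was left out and 5.82 when control array 3 was. Tead1, a transcription factor of the Hippo pathway, differed by 3.11, Prkar1a, a regulatory subunit of protein kinase A, by 1.35, and Ufm1, a ubiquitin-like modifier, by 1.05. Toward lower values, Nyap1 and Acat3 differed by -1.86 each, the chromatin helicase gene Chd4 by -1.45 (0.071 without ADI array 3) and the synaptic vesicle gene Sv2b by -1.23. With single arrays left out, Tead1 ranged from 1.42 to 4.78 and Prkar1a from 0.86 to 1.96 (without control arrays 2 and 3), and Ufm1 from 0.15 to 1.88 (without ADI arrays 1 and 3). Without ADI array 3, Nyap1, Acat3 and Sv2b were at -0.70, -0.69 and -0.70. Relative to the shift, Plcb4 was at 4.81, Tead1 at 4.01, Prkar1a at 2.25, Ufm1 at 1.95, Nyap1 and Acat3 at -0.95 each, Chd4 at -0.55 and Sv2b at -0.33. These values were 2.94 for Plcb4 and 2.40 for Tead1 without control array 2, and Chd4 turned to 0.17 without ADI array 3 and Sv2b to 0.018 without ADI array 1. None of these 8 passed the test in limma, with an adjusted p of 0.889 for each. The count of features past the threshold in limma was 0 of 5021, with 2 at an unadjusted p under 0.05. With each array centred on its median it also called 0, with 41 at an unadjusted p under 0.05. A fit of these 2 groups alone called 1 feature, and 0 with centred arrays or with the replicate number as a block. Quality weights for arrays called 2306, with weights that had not converged.

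The authors' deposited table lists 9 genes higher and 13 lower in ADI mice. Its mean log2 fold changes are 2.88 for Plcb4, 2.09 for Prkar1a, 2.03 for Ufm1 and 1.54 for Tead1. The table gives -1.16 for Apoa1, the main protein of high-density lipoprotein, and -1.43 for Sv2b. For Chd4 the authors' deposited table gives 1.55, the opposite sign to the intensities.

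Flour of conventional potatoes was compared with water. Plcb4 was at 12.65 ± 1.40 (log2, SD, n = 3) in PC mice, 3.42 above controls as deposited, with 1.47 without control array 2 and 5.34 without control array 3. Tead1 differed by 1.84 (0.15 without control array 2 and 3.51 without control array 3), Aebp2, a cofactor of Polycomb repressive complex 2, by 1.47 and Noc4l, a ribosome biogenesis gene, by 1.30. Chd4 differed by -3.02, the transcription factor gene Thap1 by -2.78, the class I histocompatibility gene H2-K2 by -2.44 and Sv2b by -2.12. Relative to the shift those 4 values are -1.46, -1.23, -0.89 and -0.57, and Plcb4, Tead1, Aebp2 and Noc4l are at 4.98, 3.39, 3.02 and 2.85. Of these, Plcb4 was at 3.10 and Tead1 at 1.77 without control array 2. H2-K2 was at -0.56 without PC array 1 and -1.43 without PC array 3, and Sv2b at -0.34 without PC array 2 and -0.96 without PC array 3. The adjusted p was 0.559 for each of the 8 genes. In limma 0 features passed, with 41 at an unadjusted p under 0.05, and 0 with centred arrays, with 269 at an unadjusted p under 0.05. A fit of the PC and control arrays alone called 3519 features, 72 higher and 3447 lower. In that fit with arrays centred on their medians, it called 0, with a smallest adjusted p of 0.051. The authors' deposited table lists 4 genes higher and 23 lower, among them Thap1 at -2.34, Marveld1 at -2.31, Nyap1 at -2.30, Apoa1 at -1.80 and the acetyltransferase gene Nat2 at -1.74.

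Flour of organic potatoes was compared with water. Aebp2 was at 12.50 ± 0.21 (log2, SD, n = 3) in PO mice and 11.48 ± 1.14 (SD, n = 3) in controls, a difference of 1.02. Noc4l differed by 1.00, Uhrf1bp1 by 0.85 (-0.10 without PO array 2) and the activin receptor gene Acvr1b by 0.70 (0.016 without PO array 3 and 2.04 without PO array 2). Ufc1, the conjugating enzyme for Ufm1, was at 7.37 ± 0.28 (SD, n = 3) against 11.91 ± 1.10 (SD, n = 3), a difference of -4.55. Chd4 differed by -3.85, Thap1 by -3.82 and Ufm1 by -3.63, and Thap1 was at -0.65 without PO array 2 and -5.97 without PO array 3. Aebp2 and Noc4l were at 0.54 and 0.62 without control array 2 and at 1.65 and 1.62 without control array 3. Relative to the shift, Aebp2 was at 3.00, Noc4l at 2.98, Uhrf1bp1 at 2.83 and Acvr1b at 2.68, and Ufc1, Chd4, Thap1 and Ufm1 were at -2.57, -1.87, -1.84 and -1.65. Without PO array 2 these values were 1.15, 1.14, 0.033 and 2.18, and -4.27, -2.54, -0.51 and -3.81, and without PO array 3 Aebp2 was at 4.59 and Ufm1 at -0.060. Aebp2 and Noc4l did not follow array brightness, with intensities of 5843 and 8681 on PO array 2. Their SD in PO mice was 0.21 and 0.48 as deposited and 3.24 and 3.34 in centred intensities, and it also rose with centring in PC and POS mice. Their values relative to the shift are therefore uncertain. Adjusted p values were 0.344 for the 4 lower genes and between 0.50 and 0.66 for the 4 higher ones. None of the 5021 features passed in limma, with 523 at an unadjusted p under 0.05, and 0 with centred arrays, with 1039 at an unadjusted p under 0.05 and a smallest adjusted p of 0.078. Without PO array 3 the count was 2936, all lower, which leaves PO arrays 1 and 2. The authors' deposited table lists only Noc4l, at 0.84, and Aebp2, at 1.00, in PO mice.

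Flour of stored conventional potatoes was compared with water. Plcb4 was at 13.55 ± 1.65 (log2, SD, n = 3) in PCS mice, 4.32 above controls, with 2.37 without control array 2 and 6.24 without control array 3. Acvr1b differed by 2.74, Card14, a scaffold of NF-kB signalling, by 2.58 and the splicing factor gene U2af2 by 2.56. Chd4, Nyap1, Acat3 and Ufc1 differed by -1.63, -1.37, -1.23 and -0.96, and Ufc1 turned positive without PCS array 1 (0.033) and without PCS array 2 (0.11). Chd4 was at -0.57 without PCS array 2, and Nyap1 and Acat3 at -0.69 and -0.65 without PCS array 1; without PCS array 3, Chd4 was at -3.57, Nyap1 at -2.18 and Acat3 at -1.997. Relative to the shift, Plcb4, Acvr1b, Card14 and U2af2 were at 4.49, 2.91, 2.74 and 2.73, and Chd4, Nyap1, Acat3 and Ufc1 at -1.46, -1.20, -1.07 and -0.80. Of these, Plcb4 was at 2.60 without control array 2, and Acvr1b at 4.81, Card14 at 4.33, U2af2 at 4.40 and Chd4 at -2.65 without PCS array 3. Without PCS array 2, Chd4 was at -0.56 and Ufc1 turned to 0.12. All 8 had an adjusted p of 1.00. The limma count was 0, with 50 features at an unadjusted p under 0.05 and 231 with centred arrays, where it also called 0. In a fit of these 2 groups alone Plcb4 was the 1 feature called, and 0 were called with centred arrays. The authors' deposited table lists 22 genes, all higher, among them Csf2, which encodes the growth factor GM-CSF, at 2.73, Card14 at 2.51, the T cell adhesion gene Cd2 at 1.67 and Slc10a1, a bile acid transporter gene, at 2.12. In the intensities Csf2 was at 10.74 ± 1.79 (SD, n = 3) in PCS mice and 8.94 ± 0.96 (SD, n = 3) in controls, and Cd2 at 11.13 ± 1.15 (SD, n = 3) and 9.26 ± 0.59 (SD, n = 3).

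Flour of stored organic potatoes was compared with water. Plcb4 was at 12.27 ± 1.17 (log2, SD, n = 3) in POS mice, 3.04 above controls, with 1.09 without control array 2 and 4.96 without control array 3. Aebp2 differed by 1.99, Noc4l by 1.73 and Acvr1b by 1.36, and Chd4, Thap1, Nyap1 and Acat3 by -2.43, -1.50, -1.40 and -1.35. Without POS array 3, Thap1, Nyap1 and Acat3 were at -0.82, -0.76 and -0.69, and without POS array 2 at -2.22, -2.20 and -2.12. Relative to the shift, Plcb4, Aebp2, Noc4l and Acvr1b were at 3.57, 2.52, 2.26 and 1.88, and Chd4, Thap1, Nyap1 and Acat3 at -1.90, -0.97, -0.87 and -0.82, with Plcb4 at 1.66 without control array 2 and Noc4l at 1.45 without POS array 3. The adjusted p was 0.999 for each. The limma count was 0, with 17 features at an unadjusted p under 0.05, and 0 with centred arrays, with 237 at an unadjusted p under 0.05. A fit of these 2 groups alone called 11, and 0 with centred arrays. In the authors' deposited table a total of 22 genes are listed, with Aebp2 at 2.48 and Noc4l at 2.00. The 3 POS cells of Uhrf1bp1 there are linear ratios, with a mean of 0.10 on the log2 scale.

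**Figure D2:**
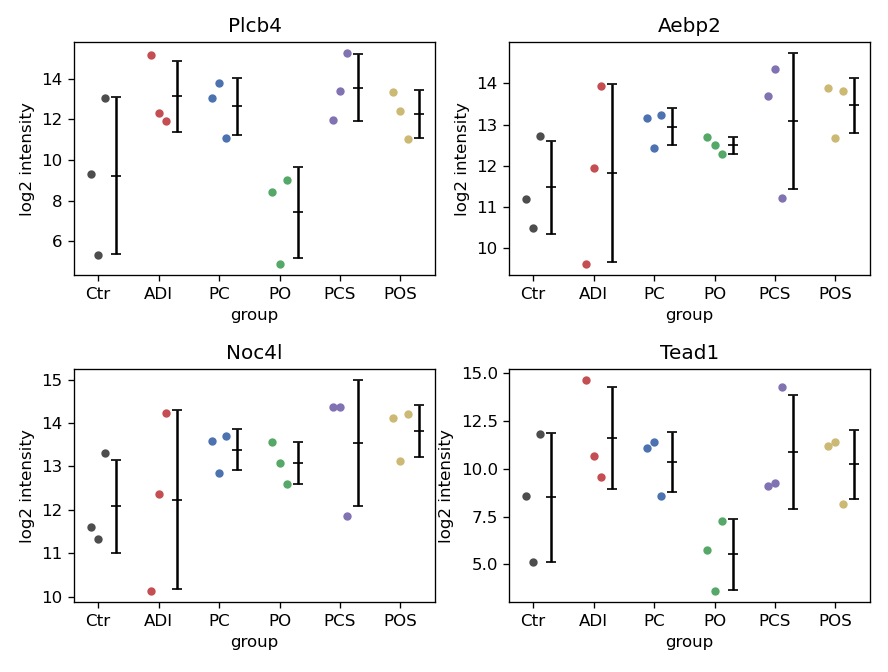
Log2 intensity of Plcb4, Aebp2, Noc4l and Tead1 (vertical axes) in the 6 groups (horizontal axes). Points are single mice, and the dash with its bar is the mean ± SD of 3 mice; Plcb4 spans 9.22 ± 3.86 in controls and 13.13 ± 1.77 in ADI mice.

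The cultivation system was compared without storage, as PC against PO. Plcb4 was higher in PC mice by 5.23 and Tead1 by 4.82, Ufm1 by 2.87 and Ufc1 by 2.74, where the median feature was 0.47 higher. Without PO array 2 the median feature was at -1.38 and without PO array 3 at 1.87, and 7 of 43 named genes were higher in PC mice without PO array 2, against 33 with it. Uhrf1bp1, Card14, Rasgef1a and Orc5 differed by -0.97, -0.34, -0.29 and -0.26. Card14, Rasgef1a and Orc5 turned positive without PO array 1 and without PO array 3, and Rasgef1a and Orc5 also without PC array 3. Uhrf1bp1 was at -0.019 without PO array 2, and at 1.40 without it in centred arrays. The adjusted p was 1.00 for each. In limma 0 features passed, with 11 at an unadjusted p under 0.05, and 0 with centred arrays, with 752 at an unadjusted p under 0.05.

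The cultivation system was compared with storage, as PCS against POS. Uhrf1bp1 was at 9.20 ± 1.74 (log2, SD, n = 3) in PCS mice and 6.81 ± 0.43 (SD, n = 3) in POS mice, a difference of 2.40. The median feature was 0.33 higher in PCS mice, but at -0.45 without PCS array 3, -0.26 without POS array 3 and 0.95 without PCS array 1. Card14, Acvr1b and Cd2 differed by 1.41, 1.39 and 1.38, and Aebp2 and Noc4l by -0.38 and -0.28, both turning positive without PCS array 3. Card14, Acvr1b and Cd2 were at 0.84, 0.60 and 0.81 without PCS array 2, and at 2.24, 2.54 and 1.96 without PCS array 3. The adjusted p was 1.00 for each gene. None passed in limma, with 2 at an unadjusted p under 0.05, and 0 with centred arrays, with 15 at an unadjusted p under 0.05. In the authors' deposited table the same 22 genes are listed for PCS and POS, both set against the same controls, and the PCS mean is above the POS mean in 21 of them. Csf2 stands there at 2.73 and 0.82, and Acvr1b at 2.86 and 0.80. The POS cells of Uhrf1bp1 there are linear ratios. A further 14 POS cells, those of POS mice 1 and 3 for Acvr1b among them, were not resolved, so their scale is not verified.

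Storage was compared over both cultivation systems. Plcb4 was 2.87 higher in the stored groups, Tead1 2.62, Ufc1 2.16 and Ufm1 1.99, where the median feature was 1.47 higher, 0.52 without PO array 2 and 2.17 without PO array 3. Relative to that shift the 4 values are 1.40, 1.15, 0.69 and 0.52, and without PO array 2 they are 1.71, 1.61, 1.57 and 1.62. Without PO array 3, Ufc1 was at 0.060 and Ufm1 at -0.24 relative to the shift. Without PCS array 3, Ufc1 and Ufm1 were at 1.13 and 1.19. All 43 named genes were higher as deposited, with and without PO array 2, and 33 were above the shift with it and 21 without it. The adjusted p was 0.297 for each of the 4. None passed in limma, with 87 at an unadjusted p under 0.05, and 0 with centred arrays, with 63 at an unadjusted p under 0.05.

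The interaction asks whether the PCS to POS difference departs from the PC to PO difference. Uhrf1bp1 was at 3.37, Card14 at 1.75, Acvr1b at 1.57 and U2af2 at 1.51. The median feature was at -0.16, at 1.75 without PO array 2 and at -1.59 without PO array 3. Tead1 was at -4.18, Plcb4 at -3.95, Ufm1 at -2.64 and Ufc1 at -2.63. Without PO array 2, Card14, Acvr1b and U2af2 were at 3.27, 2.92 and 3.02. Acvr1b was at 0.78 without PCS array 2, and Card14 and U2af2 were at 0.87 and 0.72 without PO array 3. Ufm1 and Ufc1 were at -4.24 and -4.70 without PCS array 3, and at -1.78 and -1.56 without PCS array 2. Of the 43 named genes, 11 were above 0, and 36 without PO array 2. The adjusted p was 1.00 for each. None passed in limma, with 1 at an unadjusted p under 0.05, and 0 with centred arrays, with 356 at an unadjusted p under 0.05.

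The intensities were also put through the fold rule in the header of the authors' deposited table, by which every mouse of a group lies above 2 or below 0.5 times the control mean. Among 5021 features, 23 passed in ADI mice, 2373 in PC, 221 in PO, 53 in PCS and 68 in POS. After median centring the counts were 22, 218, 354, 42 and 127, and the split turned from 0 higher and 23 lower to 13 and 9 in ADI mice, from 43 and 2330 to 165 and 53 in PC, from 6 and 215 to 89 and 265 in PO, from 47 and 6 to 13 and 29 in PCS and from 25 and 43 to 80 and 47 in POS. The 19 other assignments of the same 6 arrays gave as deposited up to 511, 2661, 2127, 1064 and 568. They include the real grouping with controls and treated mice swapped, so these maxima need not come from mixed groups. Of the genes the authors list, 17 of 21 passed in PC mice in the listed direction, including Thap1 and Nyap1, and 3 of 21 after median centring. As deposited, 0 of 18 passed in ADI, 0 of 2 in PO, 0 of 20 in PCS and 0 of 20 in POS, and after median centring 3, 0, 1 and 3.

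A further 1893 features have a blank PCS cell and were left out of the comparisons above. In them several column medians sit elsewhere than in complete rows: the median log2 ratio to the controls was 0.85 for PO array 2, 1.36 for PCS array 2 and 0.48 for POS array 1, against -5.67, -0.50 and -0.50 in complete rows. The PO array 1 column was at -1.35 in them and at -1.13 in complete rows. The genes S100a14, Plscr1, Shank3, Katnal2, Neil3, Bop1, Apom and Trbv13-1 are among these features.

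**Figure D3:**
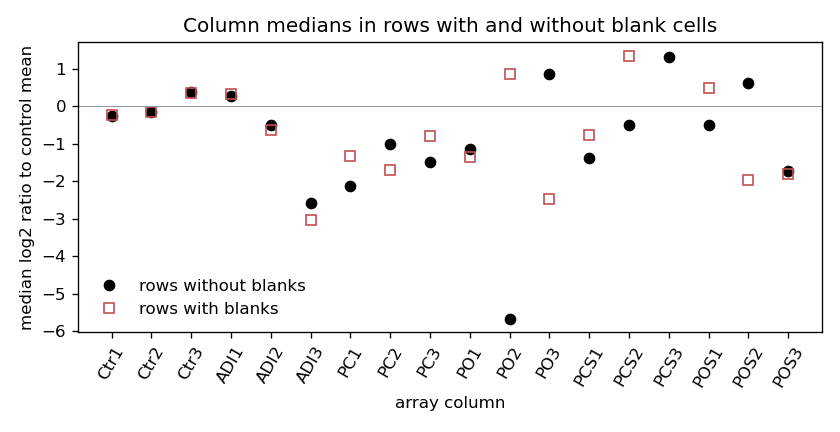
Median log2 ratio to the control mean (vertical axis) of each array column (horizontal axis) over the 5021 features without blanks (filled circles) and the 1893 with blanks (open squares). PO array 2 is at -5.67 in the first and 0.85 in the second; PCS array 3 has no value in the second.

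The 2 deposited tables gave the same sign for 79 of 80 gene and group pairs, the exception being Chd4 in ADI mice. Uhrf1bp1 in POS mice, with its linear ratios, was left out. The 80 include POS pairs with unresolved cells, all 3 cells for Orc5, Slc10a1 and Rasgef1a and some for Acvr1b and U2af2. These were read as log2 values. As linear ratios, Orc5, Slc10a1 and Rasgef1a would have the opposite sign to the intensities. Within a group the median SD of the log2 values was 0.14 in the authors' deposited table, 1.40 in the intensities and 0.68 in centred intensities, over 75 gene and group sets. The SD was smaller in the authors' deposited table than in the uncentred intensities in 75 of the 75 sets. Of 285 non-zero cells in the authors' deposited table, 268 equal the log2 of a whole number over the mean of 3 whole-number controls, within a relative tolerance of 1e-14. A further 3 cells equal such a ratio on the linear scale and 14 cells were not resolved, all of them in POS mice. In features without blanks, at least 84 of 231 whole numbers from both kinds of cell equal the deposited intensity of the same mouse. The recovery missed equal cells in PC mice 2 and 3, where the numbers had lost a shared factor. For Thap1 it gave 1735 and 1426 for intensities of 3470 and 2852, and for Chd3 443 and 417 for 3101 and 2919. The control sum behind the folds equals the deposited control sum in 4 of 51 genes. Although the header sets folds between 0.5 and 2 to 0, 95 non-zero cells lie in that range, 59 of them in POS mice.

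**Figure D4:**
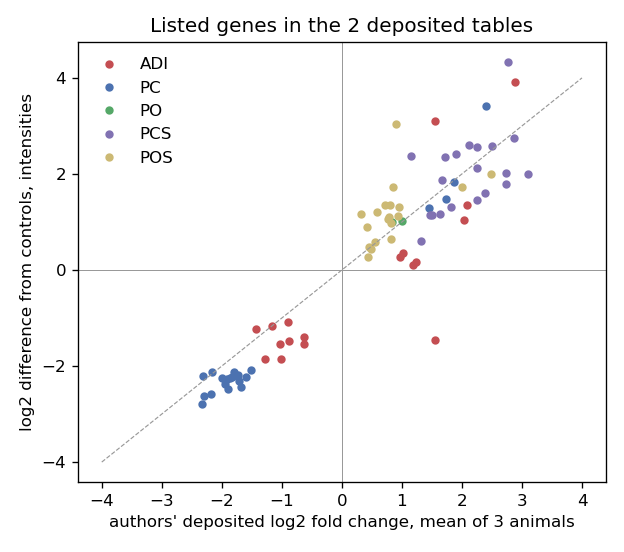
Mean log2 fold change over 3 mice in the authors' deposited table (horizontal axis) against the log2 difference from controls in the deposited intensities (vertical axis), for 80 pairs of a listed gene and a group, coloured by group. The dashed line marks equal values. With unresolved POS cells read as log2 values, 79 pairs have the same sign in both.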

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

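Tests in this part were chosen after the results were seen, among them the fits without PO array 2 in centred arrays. The exceptions are median centring, the comparison with a level predicted from array brightness and the share of simulated changes called. How the count with median centring would bear on array brightness was written down only after that count was known. For the fits without PO array 2 it was written down before they were run.

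In the 1893 rows with a blank PCS cell, which the comparisons of the report left out, PO array 2 lay above the highest control in 1349 rows, against 74 of the 5021 complete rows, and its median log2 ratio to the controls was 0.85 in rows with blanks and -5.67 in complete rows. Features missing in PCS mice would leave PO array 2 dim, so that value argues against this biological reading. In 8 named genes with blanks, 11 of 24 whole numbers behind the authors' deposited folds equal the intensity cell 1 column to the left and 0 equal the cell of the same column, against 0 shifted matches in complete rows; these numbers lie in PC and PCS columns. A candidate explanation for those columns is that cells moved 1 column to the left. A move of the whole row is argued against by the PO array 1 column, which would hold PO array 2 and was at -1.35, and what the PO and POS columns hold there stays open.

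The whole numbers behind the authors' deposited folds differ from the deposited intensities in at most 147 of 231 cells of complete rows, since the recovery missed equal cells for Thap1 and Chd3. A scale factor per array is argued against, since 12 of 15 arrays hold both equal and differing cells. Of these 147 cells, 72.8% are within 1 digit of the intensity (a digit changed, added or dropped), against 0.58% when set against another mouse of the same gene. A multiple of 100 separates 89.8% of them from the intensity, against 1.17% for another mouse, so the last digits mostly agree. Both shares go with changes to digits in either file, mainly leading digits and in some cells more than 1. Which file departs from the scan cannot be told apart here: the number behind the fold was closer to the level predicted from controls and array brightness in 52.4% of differing cells. Both tables describe the same mice, so no biological explanation was tested.

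Limma called 0 features in each of the 9 comparisons as deposited. After median centring 0 features passed, and 0 over the 9 comparisons when PO array 2 was also left out. These counts do not decide whether array brightness or PO array 2 was the whole reason, since both rest on centring. Centring takes 1 median from each array. It lowered the median SD over 75 gene and group sets from 1.40 to 0.68 but raised the SD of some genes, for Aebp2 in PO mice from 0.21 to 3.24. Whether large effects are absent stays open. As deposited, at most 46% of simulated 8-fold changes were called, a share that mixes rises and falls set on the real array brightness. With centred arrays 76% to 86% were called in 8 of 9 comparisons and 42% for the interaction, and the real count was 0 in each. Simulated changes of 2-fold were called there in only 2% to 24%, and changes of 4-fold in 28% to 84%, so smaller changes could be missed. The simulation spreads the extra noise of PO array 2 over every array, which the real data do not. With a real count of 0 every split of the arrays has as many features by construction (10 of 10 in each of the 7 comparisons of 3 arrays with 3, with a highest other of 0, and 100 of 100 for storage and for the interaction, with a highest other of 0 and 4093), so the splits decide nothing. What gave the split with 4093 was not tested.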

How the results depend on the processing

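Median centring, quantile normalization, a pseudocount of 16, leaving out the dimmest 25%, trend with robust, and a fold of at least 1.5 beside the adjusted p each gave 0 features in all 9 comparisons. Over all groups the replicate numbers showed no clear pairing of the mice, which does not rule pairing out. Of 45 same-numbered pairs of arrays, 19 correlate over 0.1 (lowest -0.76), and 18 correlate best with their own number. With the replicate number as a block the count was 0 in all 9 comparisons. Only control and ADI arrays correlated best with their own number for every replicate number (0.41, 0.52 and 0.31). These groups were picked from all pairs of groups after the values were seen, which does not show that the mice were paired. A limma fit of these groups alone with the replicate block, added after seeing this, called 0 for ADI as deposited (smallest adjusted p 0.114) and 0 with centring (0.705). Settings chosen after seeing the data that also gave 0 throughout are all 6914 rows, the 75th percentile, a pseudocount of 16 with quantile normalization, PO array 2 left out with centring, and only the compared groups with centring. No list test, and no averaging of features of a gene, could be run. Values near the background, as on PO array 2, limit every PO result. Through the shared estimate of the spread, PO array 2 also bears on comparisons without PO mice. In limma with centred arrays, leaving it out moved the smallest adjusted p from 0.640 to 0.213 for PC. It moved from 0.868 to 0.374 for PCS and from 0.797 to 0.313 for POS, with 0 features called in each.

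Other settings gave calls, and the cause was not tested except where said. Default array weights, whose fit stopped before converging (weights from 1.57e-11 for PO array 1 to 4974 for ADI array 2), gave 2306 features for ADI, 4330 for PC, 3291 for PCS, 3103 for POS and 4031 for PCS against POS, 1975 higher and 2056 lower in the last. Gene by gene weights, added after that, gave 39 for ADI, 3899 for PC, 2609 for PO, 1787 for PCS, 980 for POS, 64 for PC against PO, 370 for PCS against POS, 3469 for storage and 381 for the interaction. Only the compared groups gave 1 for ADI, 3519 for PC, 1 for PCS and 11 for POS, and 0 for each with centring. An unadjusted p with a fold of at least 1.5 gave 2 for ADI, 41 for PC, 523 for PO, 50 for PCS, 17 for POS, 11 for PC against PO, 2 for PCS against POS, 87 for storage and 1 for the interaction. Leaving out single arrays gave 0 in 65 of 66 fits, POS array 3 among them, and ranged from 0 to 2936 for PO, the highest without PO array 3.

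The fold rule, applied after seeing the data, gave 15 features in ADI with a pseudocount of 16 and 38 with all rows, 218 in PC with centring and 218 with quantile normalization, 354 in PO with centring, 25 in PCS with a pseudocount of 16, and 127 in POS with centring, 112 with quantile normalization and 105 with all rows. In PC its split turned from 43 higher and 2330 lower to 165 and 53 with centring.

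Of 1408 recomputed gene differences, 1288 kept their direction and side of the threshold, 98 passed it in the same direction and 22 turned, 2 of them also passing it. Default weights gave 0.47 for Thap1 in PO, and, past the threshold in the opposite direction, 0.47 for Aebp2 and 0.26 for Noc4l in PCS against POS. Gene by gene weights gave -0.53 for Uhrf1bp1 in PO, 0.24 for it in PC against PO, 0.43 for Aebp2 and 0.27 for Noc4l in PCS against POS. Without PO array 2 and with centring, Uhrf1bp1 in PC against PO was 1.40. Leaving out a single array turned or moved 40 of 66 gene differences by over 1.5 times, and 46 of 66 taken relative to the median shift, 7 of which turned. Over single arrays left out, Chd4 in ADI ranged from -3.19 to 0.071, Uhrf1bp1 in PO from -0.10 to 1.62 and Ufc1 in PCS from -3.03 to 0.11. In PC against PO, Orc5 ranged from -1.71 to 0.53, Card14 from -1.86 to 0.54 and Rasgef1a from -1.63 to 0.40. In PCS against POS, Aebp2 ranged from -1.02 to 0.55 and Noc4l from -0.70 to 0.56.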
